A study of Homo sapiens with 6 samples.

How the data were processed

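Gene expression was measured with Affymetrix whole-transcript arrays in primary human umbilical vein endothelial cells (HUVEC), a widely used culture model of the cells that line blood vessels. Cells between passages 2 and 4 received the solvent dimethyl sulfoxide (DMSO), telmisartan at 100 µmol/L, or telmisartan at 100 µmol/L with amlodipine at 5 µmol/L, for 24 hours. Telmisartan blocks the angiotensin II type 1 receptor and is a partial agonist of the nuclear receptor PPARγ, and amlodipine blocks voltage-gated calcium channels. Each of the 3 groups held 2 arrays, which the labels call biological replicates without saying whether they came from separate donors. The p-values therefore measure the spread between these arrays. Cells given amlodipine alone, which the study's design also names, were not analysed here.

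The values deposited by the authors are log2 expression values, 1 per transcript cluster (the probes that target the same transcribed region) and array. Per the submitters' processing notes, the software was Affymetrix Expression Console 1.2, and the method named is GCRMA, which corrects probe signals for background by their sequence; the order and settings of these steps, and the genome build, are not given in the sources used here. The table held 33297 rows. The sorted values of the 6 arrays were close but not identical, with medians from 7.07 to 7.10, so no further normalization was applied in the main analysis. No gene centring was seen in the deposited values. Arrays have no read depth, and the number of arrays limits the precision.

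Rows were named from the array's annotation. A total of 19460 rows had 1 gene symbol, 1754 had several, and 12083 (36.3%) were not named here. Of the rows with 1 symbol, 19429 matched the human gene table (assembly GRCh38.p14, used for names and gene lengths only) by Entrez gene number, with 0 symbols changed. Only rows with 1 symbol were tested. For the 769 genes with more than 1 transcript cluster, the cluster with the highest mean over the 6 arrays was kept, which left 18417 genes.

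Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 6 arrays, with a term for group only and 1 estimate of the spread shared by the 3 groups. The fit left 3 residual degrees of freedom, to which moderation added 5.01. The p-values were adjusted with the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Errors given with log2 differences are limma's standard errors, and intervals are 95% confidence intervals. With 2 arrays against 2, an exact permutation test of a single gene cannot give a p below 0.333, so none was used.

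A set of 43 gene lists covered pathways and cell types relevant to endothelial cells and these drugs. They named 887 genes, of which 815 were measured. Each list was tested with limma's camera, a competitive test of a list against all other genes, with a preset inter-gene correlation of 0.01, and adjusted over the lists within a comparison. Camera with an inter-gene correlation estimated from the residuals, and fry, were run beside it. With an estimated correlation, camera's p-values rest on the 3 residual degrees of freedom, which leaves the test little power. Targets of p53, with an estimated correlation of 0.0085, went from an unadjusted camera p of 0.024 to 0.105 for the combination against DMSO. A call lost in this setting therefore does not by itself show that the call was false. Fry tests a list against no change rather than against the other genes, so it asks a different question. The lists, the comparisons, the tests and most alternative settings were fixed before the data were examined.

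Genes were named by a rule. Up to 10 called genes with the largest rise and 10 with the largest fall would be named, if both arrays of one group lay beyond both arrays of the other. Where too few genes passed, as happened here, the 5 genes with the largest absolute log2 difference that kept this order were named as not called, together with a fixed set of genes for cell cycle control, vascular tone and the drug targets. Placeholder symbols and small RNA genes were never named. Members of lists given as examples were chosen after their values were seen, among those with the largest differences in the list's direction whose 4 arrays kept their order. Genes called over a list alone were also named after their values were seen.

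The analysis was checked on simulated data before use. With independent noise for all 18417 genes, telmisartan against DMSO, and 200 genes changed, the fit recovered 73.3% of genes changed 1.5-fold and 99.6% of those changed 2-fold, with 7.70% false calls in the latter case. When the shift was instead added to the deposited values of 200 genes, the fit of telmisartan against DMSO recovered 0% at 1.5-fold, 93.6% at 2-fold and 99.85% at 4-fold. The same test gave 93.45% at 2-fold for the combination against DMSO and 93.6% for the combination against telmisartan. A shift of -0.2 in a list of mitotic genes was recovered in 10 of 10 simulated draws with independent noise. In the arrays themselves these genes had an estimated inter-gene correlation of 0.252, so this does not show that such a shift was detectable there.

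Alternatives covered the replicate number as a block, fits on the 4 arrays compared, trended and robust moderation, 3 other scalings, array weights, filters on dim genes, other treatments of transcript clusters, a minimum fold of 1.5, leaving out each array in turn and other tests of lists. A block with crossed replicate numbers, and tests of every row of the table, were added after seeing the data. Left out were rows with several gene symbols or none.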

Results

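Expression of 18417 genes was compared in HUVEC treated for 24 hours with DMSO, with 100 µmol/L telmisartan, or with 100 µmol/L telmisartan and 5 µmol/L amlodipine, on 2 arrays per group. Array medians over all rows ranged from 7.07 to 7.10 on the log2 scale. The endothelial genes KDR and NOS3 were bright in the DMSO cells, while VCAM1, an adhesion molecule gene, was dimmer at 6.44 ± 0.03 (SD, n = 2). KDR, the main receptor for vascular endothelial growth factor, had a log2 expression of 11.96 ± 0.17 (SD, n = 2), and NOS3, the endothelial nitric oxide synthase, one of 11.01 ± 0.03 (SD, n = 2). The gene of telmisartan's receptor, AGTR1, was dim at 5.45 ± 0.11 (SD, n = 2), as was PPARG at 5.643 ± 0.0025 (SD, n = 2).

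Differences between replicates were as large as those between treatments. The log2 values of the replicate arrays differed with an SD over genes of 0.185 for DMSO, 0.176 for telmisartan and 0.229 for the combination. DMSO replicate 1 and telmisartan replicate 1 differed less, with an SD of 0.130. The first principal component held 46.3% of the variance, and 13.9% of the variance of its scores lay between the treatment groups. It placed DMSO replicate 1, telmisartan replicate 1 and combination replicate 2 on one side. Genes with large differences along it included ANKRD36B, an ankyrin-repeat gene, with replicate 1 minus replicate 2 at 0.88 in DMSO, 1.01 in telmisartan and -0.84 in the combination. DLGAP5, a mitotic spindle gene, had 0.71, 0.69 and -0.90 in the same order. Both were chosen after their values were seen.

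**Figure D1:**
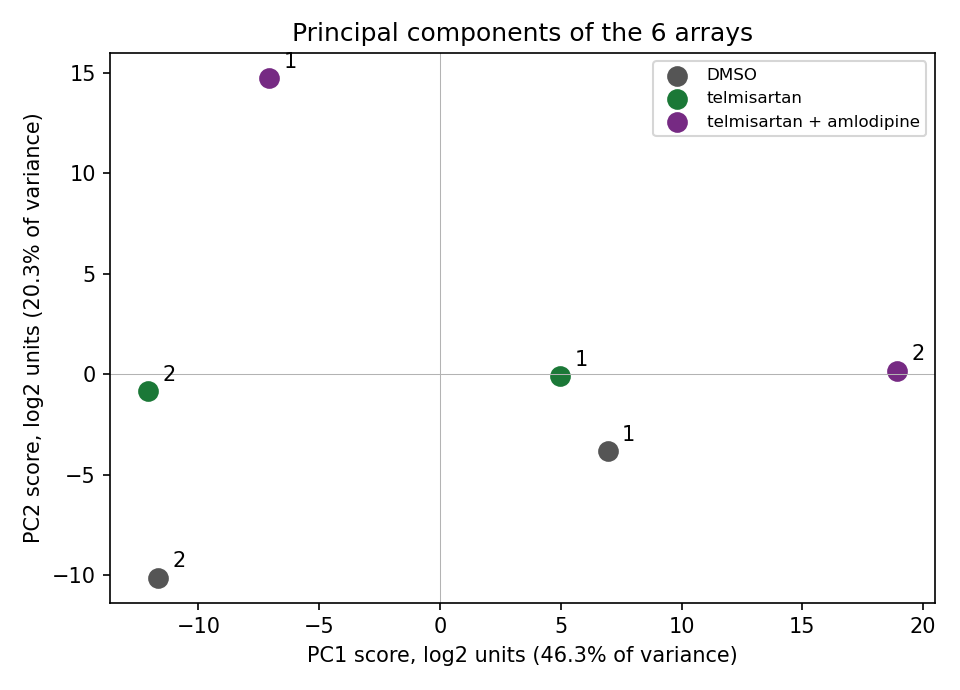
Scores of the 6 arrays on the first and second principal components of log2 expression (log2 units), coloured by treatment, with replicate numbers beside the points. Along the first component, with 46.3% of the variance, the replicates of each group lie on opposite sides of 0.

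The first comparison asked which transcripts differed between telmisartan and its solvent. The thioredoxin inhibitor gene TXNIP had the largest difference that kept the order of all 4 arrays, at -0.93 ± 0.27 (SE, n = 2 per group), with a 95% confidence interval of -1.54 to -0.31. H2BC12, a histone H2B gene, had a mean of 8.43 ± 0.08 (SD, n = 2) with telmisartan and 9.33 ± 0.02 (SD, n = 2) with DMSO, a difference of -0.90 ± 0.11 (SE). The bitter taste receptor gene TAS2R31 differed by 0.67 ± 0.18 (SE), CRIPTO3, a copy of a NODAL co-receptor gene, by 0.61 ± 0.12 (SE), and the olfactory receptor gene OR10G4 by -0.54 ± 0.19 (SE). Single arrays set the size of some of these: TXNIP differed by -0.60 without DMSO replicate 1, TAS2R31 by 0.39 without DMSO replicate 2 and OR10G4 by -0.21 without telmisartan replicate 2. None of these differences passed the test. H2BC12 had the smallest adjusted p of all genes, at 0.793 in limma. Histone, taste receptor, olfactory receptor and CRIPTO family genes have near-identical copies, so their probes may read more than 1 gene and their values are uncertain. CRIPTO3, TAS2R31 and OR10G4 were also dim, with means of 4.44, 5.21 and 6.02 with DMSO and of 5.05, 5.88 and 5.47 with telmisartan.

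The fixed genes had small differences with telmisartan, and none passed the test. NOS3 differed by 0.15 ± 0.10 (SE, n = 2 per group; 95% confidence interval -0.07 to 0.37). CDKN1A, a cell cycle inhibitor gene, differed by -0.03 ± 0.10 (SE), and the proliferation marker MKI67 by -0.13 ± 0.21 (SE). The mitotic cyclin gene CCNB1 differed by -0.03 ± 0.09 (SE), and MCM2, part of the replicative helicase, by 0.11 ± 0.11 (SE). The adhesion molecule gene VCAM1 differed by -0.02 ± 0.14 (SE), AGTR1 by -0.02 ± 0.13 (SE) and PPARG by -0.04 ± 0.14 (SE). KDR differed by -0.02 ± 0.11 (SE), and its sign turned when the values were quantile normalized again. Leaving out 1 array turned the signs of KDR, MKI67 (0.17 without telmisartan replicate 2), VCAM1 (0.18 without telmisartan replicate 1), AGTR1, CDKN1A and CCNB1, and moved NOS3 to 0.09 without telmisartan replicate 2 and PPARG to -0.004 without telmisartan replicate 1.

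**Figure D2:**
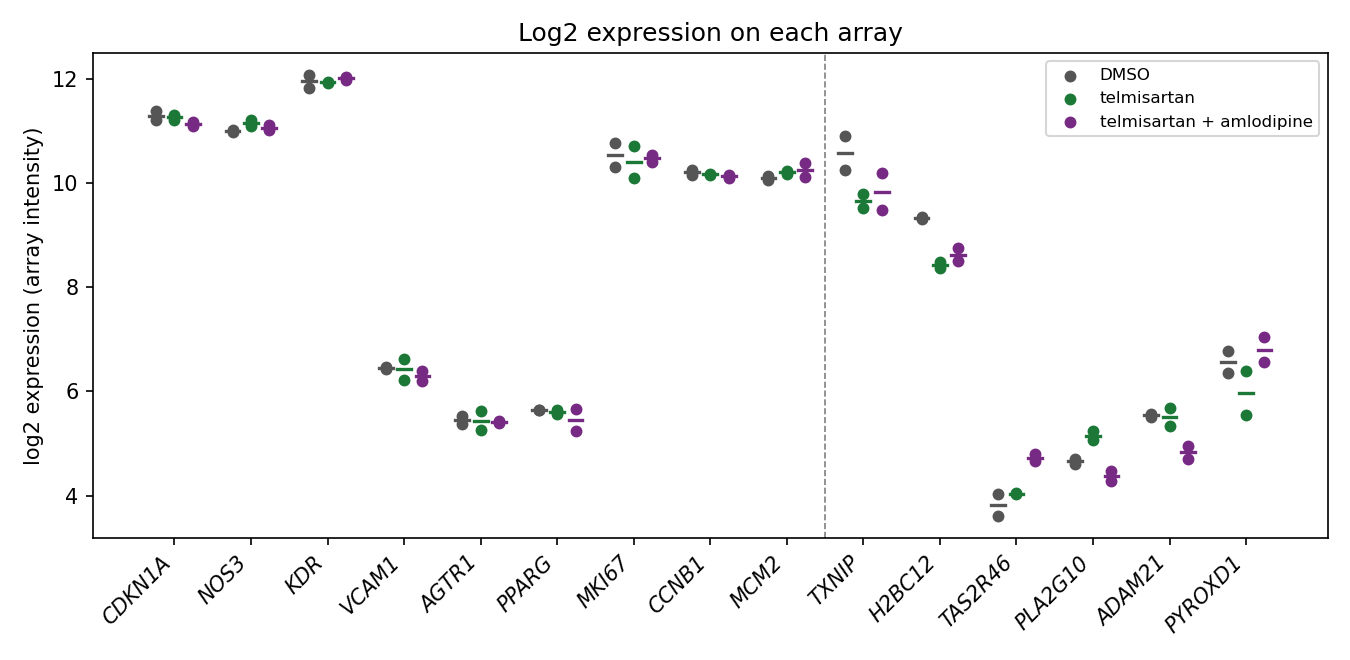
Log2 expression (array intensity) of 9 fixed genes, left of the dashed line, and 6 genes with large differences, right of it, on each array, with a short line at each group mean. Both H2BC12 values with telmisartan, mean 8.43, lie below both DMSO values, mean 9.33, and no gene shown passed the test in any comparison.

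Across all 18417 genes, limma called 0 genes between telmisartan and DMSO. An unadjusted p under 0.05 was reached by 248 genes (1.35%). Uniform p-values would give a share of 0.05, so this count lies below chance and is no sign of an effect. No gene differed by more than 2-fold, and 10 differed by more than 1.5-fold. The median log2 difference over all genes was 0.017. The order of all 4 arrays was kept for 29.6% of genes, where chance gives 33.3%. The median standard error was 0.109, and a 1.5-fold shift added to the deposited values was recovered for 0% of genes, so changes of that size were not detectable.

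As groups, 6 of the 43 gene lists lay lower with telmisartan than with DMSO in camera with the preset correlation, by less than 0.1 in the median log2 difference. None of these 6 calls held with an estimated correlation (smallest adjusted p = 0.97 with an estimated correlation), and none of the lists passed in fry (smallest adjusted p = 0.983). Camera with an estimated correlation had little power with 3 residual degrees of freedom, so its losses alone cannot count against a list. Its adjusted p was 0.97 for each of the 6, from unadjusted p of 0.089 for heat shock proteins to 0.499 for histone genes. Fry's adjusted p was 0.983 for every list, and it forms the upper end of the ranges given below for this comparison. The adjusted p given next for each list is from camera with the preset correlation. Genes of mitosis were lower for 35 of 47 members (median -0.040, adjusted p = 0.013), with SPC25, a kinetochore gene, at -0.23 ± 0.11 (SE) and AURKA, a mitotic kinase gene, at -0.20 ± 0.10 (SE). Replication-dependent histone genes were lower for 22 of 28 members (median -0.054, adjusted p = 0.013). Metallothioneins, which bind zinc and copper, were lower for 9 of 10 (median -0.056, adjusted p = 0.013), with MT1F at -0.23 ± 0.09 (SE) and MT1E at -0.13 ± 0.10 (SE). Genes of oxidative phosphorylation were lower for 21 of 28 (median -0.047, adjusted p = 0.013), with the complex I genes NDUFA2 at -0.24 ± 0.09 (SE) and NDUFA1 at -0.16 ± 0.10 (SE). Heat shock proteins were lower for 12 of 14 (median -0.074, adjusted p = 0.018), with the mitochondrial chaperone gene HSPD1 at -0.15 ± 0.10 (SE). Cytosolic ribosomal protein genes were lower for 20 of 29 (median -0.033, adjusted p = 0.044), with RPL10A at -0.21 ± 0.10 (SE), but their median turned to 0.009 when the values were quantile normalized again. In each of these 6 lists 0 members were called over all genes and 0 adjusted over the list alone.

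The estimated inter-gene correlation of the histone genes was 0.802, against the preset 0.01. It was 0.346 for metallothioneins, 0.252 for mitotic genes, 0.136 for oxidative phosphorylation, 0.057 for heat shock proteins and 0.056 for ribosomal protein genes. Members of a list were thus not separate readings, which the preset value hardly allows for. Mitotic and histone genes also followed the split of the arrays, by more than these differences: replicate 1 minus replicate 2 had medians of 0.157, 0.211 and -0.114 for mitotic genes and of -0.220, -0.300 and 0.156 for histone genes in DMSO, telmisartan and the combination. Leaving out single arrays turned the medians of the mitotic genes, to 0.025 without DMSO replicate 1 and 0.074 without telmisartan replicate 2, and of the histone genes, to 0.054 without DMSO replicate 2 and 0.085 without telmisartan replicate 1. Heat shock proteins lost their call with smaller medians, -0.026 without DMSO replicate 1 (adjusted p = 0.694) and -0.018 without telmisartan replicate 2 (adjusted p = 0.724). Other calls were lost in fits with fewer arrays while the difference stayed negative. Oxidative phosphorylation had a median of -0.026 without DMSO replicate 2 (adjusted p = 0.30), and of -0.046, close to that with all arrays, without telmisartan replicate 2 (adjusted p = 0.347). Metallothioneins had medians of -0.046 without DMSO replicate 2 (adjusted p = 0.30), -0.065 without telmisartan replicate 1 (adjusted p = 0.218) and -0.078 without telmisartan replicate 2 (adjusted p = 0.066). Ribosomal protein genes had medians of -0.041 without DMSO replicate 1 (adjusted p = 0.157), -0.032 without DMSO replicate 2 (adjusted p = 0.30) and -0.024 without telmisartan replicate 2 (adjusted p = 0.462). Over 20 alternatives, the adjusted p ranged from 6.41e-11 to 0.983 for mitotic genes, from 2.61e-11 to 0.983 for histone genes, from 0.00136 to 0.983 for heat shock proteins and oxidative phosphorylation, and from 0.00916 to 0.983 for metallothioneins and ribosomal protein genes.

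Lists tied to the drug targets were not called with telmisartan in the main setting. Targets of PPAR nuclear receptors were lower for 19 of 27 members (median -0.039, adjusted p = 0.063 in camera), with TXNIP in that list and the lipid droplet gene PLIN2 at -0.11 ± 0.09 (SE). The PPAR list passed with the dimmest genes dropped (adjusted p = 0.046 and 0.016 under the milder and the stricter filter), and its adjusted p ranged from 0.016 to 0.983 over 20 alternatives (adjusted p = 0.97 with an estimated correlation). Genes of the integrated stress response were lower for 20 of 31 (median -0.037, adjusted p = 0.064, adjusted p = 0.97 with an estimated correlation). They passed in the fit on the 4 arrays compared (adjusted p = 0.040) and without telmisartan replicate 2 (median -0.127, adjusted p = 0.010), with medians from -0.127 to 0.014 and adjusted p from 0.010 to 0.983 over 20 alternatives. Genes of the renin-angiotensin system were lower for 8 of 10 (median -0.039, adjusted p = 0.239). Nitric oxide and vasoactive genes were higher for 12 of 20 (median 0.015, adjusted p = 0.883), with the prostacyclin synthase gene PTGIS at 0.22 ± 0.10 (SE), and median centring, which shifted all genes alike by -0.029, turned their median negative. Targets of p53 were higher for 14 and lower for 14 of 28 members (adjusted p = 0.972). The growth factor gene TGFB2, at -0.43 ± 0.10 (SE), was the only gene called when adjusted over a list alone (YAP/TAZ targets, adjusted p = 0.038), against an adjusted p of 0.99996 over all genes. The sign of the median and the direction of the test differed for 8 of the 43 lists.

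**Figure D3:**
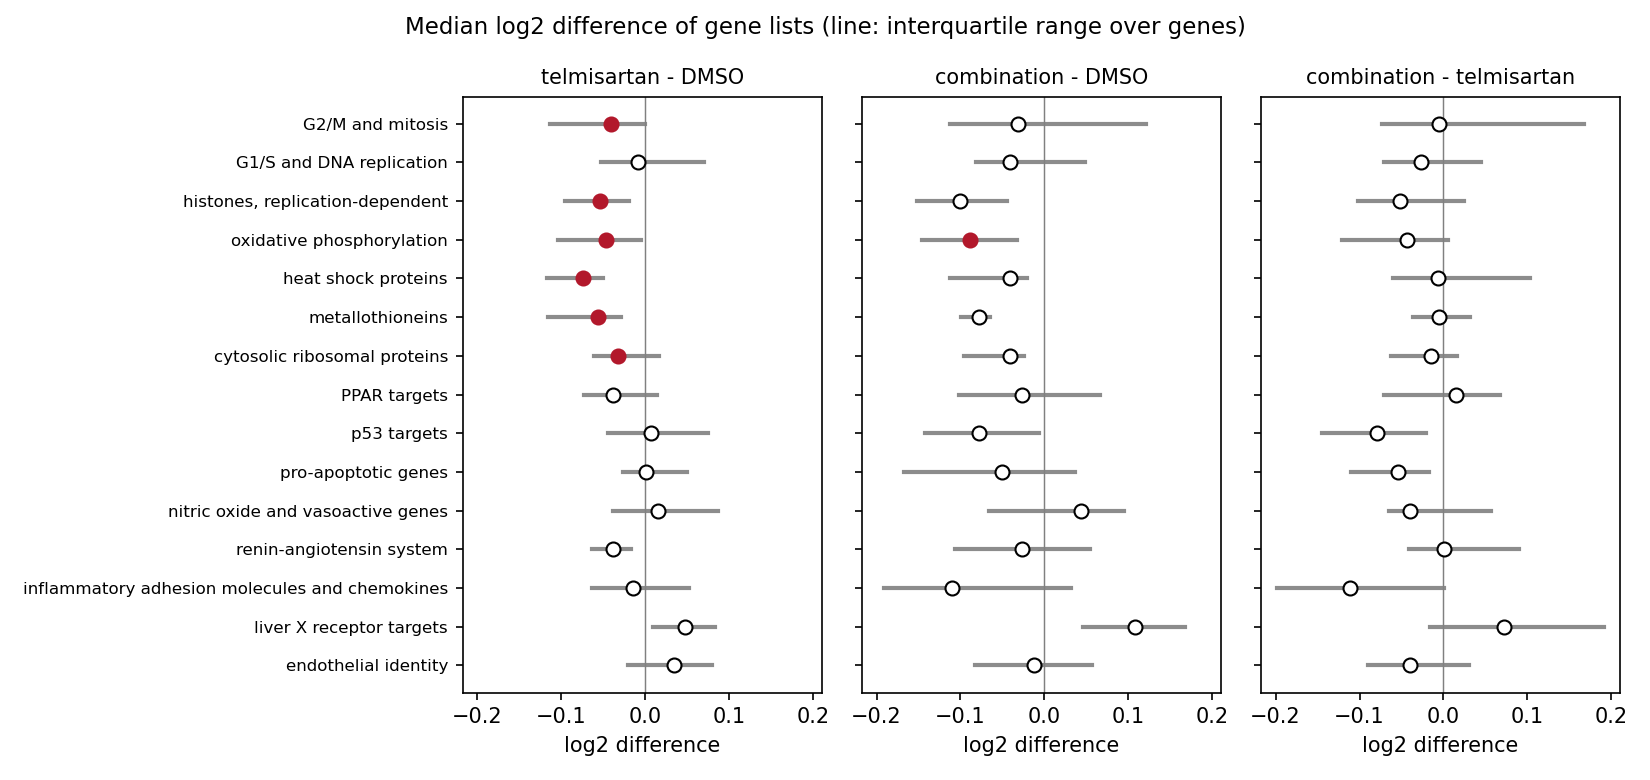
Median log2 difference of 15 gene lists in the 3 comparisons, with lines for the interquartile range over the measured genes. Filled points passed camera with the preset correlation (adjusted p under 0.05), and 0 lists passed with an estimated correlation; the median of ribosomal protein genes turned positive against DMSO when the values were quantile normalized again.

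The second comparison asked which transcripts differed between the drug combination and the solvent. The bitter taste receptor genes TAS2R46 and TAS2R31 differed by 0.91 ± 0.14 (SE, n = 2 per group) and 0.83 ± 0.18 (SE). The zinc-finger gene ZNF117 differed by 0.90 ± 0.37 (SE), but by 0.27 without combination replicate 2. ZNF117 also followed the split of the arrays across the treatment groups. Its replicates 1 and 2 had 8.35 and 7.84 with DMSO, 8.40 and 7.98 with telmisartan, and 8.37 and 9.63 with the combination. The antisense transcript THUMPD3-AS1 differed by -0.90 ± 0.17 (SE) and TXNIP by -0.75 ± 0.27 (SE), the latter by -0.39 without combination replicate 2. TAS2R31 differed by 0.55 without DMSO replicate 2. None passed the test. Taste receptor and zinc-finger genes have near-identical copies, and THUMPD3-AS1 lies next to a gene on the other strand, so these values are uncertain. TAS2R46 was dim, at 4.73 ± 0.10 (SD, n = 2) with the combination and 3.82 ± 0.29 (SD, n = 2) with DMSO.

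Among the fixed genes, PPARG differed by -0.19 ± 0.14 (SE), CDKN1A by -0.16 ± 0.10 (SE) and MCM2 by 0.15 ± 0.11 (SE) between the combination and DMSO. VCAM1 differed by -0.14 ± 0.14 (SE), CCNB1 by -0.08 ± 0.09 (SE), MKI67 by -0.07 ± 0.21 (SE), NOS3 by 0.06 ± 0.10 (SE), KDR by 0.06 ± 0.11 (SE) and AGTR1 by -0.03 ± 0.13 (SE). None of them passed the test. Leaving out 1 array turned the signs of PPARG (0.02 without combination replicate 2), MKI67 (0.16 without DMSO replicate 1), KDR and AGTR1. It moved MCM2 to 0.02 without combination replicate 1, CDKN1A to -0.08 without DMSO replicate 2, and VCAM1, CCNB1 and NOS3 by more than 1.5 times. With limma, 0 of 18417 genes were called, and the smallest adjusted p was 0.930. An unadjusted p under 0.05 was reached by 719 genes (3.90%), again below the share of 0.05 that uniform p-values would give. By more than 1.5-fold, 34 genes differed. The order of all 4 arrays was kept for 29.1% of genes, and the median log2 difference over all genes was -0.014.

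Of the 43 lists, oxidative phosphorylation was called in this comparison. It was lower for 24 of 28 members (median -0.088, adjusted p = 0.020 in camera), with NDUFA2 at -0.29 ± 0.09 (SE), the complex I gene NDUFB5 at -0.27 ± 0.10 (SE) and COX7A2, a cytochrome c oxidase gene, at -0.31 ± 0.12 (SE). In fry the list did not pass (adjusted p = 0.533), and with an estimated correlation the call was lost (adjusted p = 0.876 with an estimated correlation). It was also lost without DMSO replicate 2 (median -0.046, adjusted p = 0.141), combination replicate 1 (median -0.130, adjusted p = 0.077) or combination replicate 2 (median -0.046, adjusted p = 0.080), so the difference grew in the fit without combination replicate 1. The adjusted p ranged from 0.00441 to 0.876 over 20 alternatives. No member was called over all genes or adjusted over the list alone. In sets of arrays drawn from the within-group differences alone, 84 of 100 called at least 1 list in this comparison (median 2), so a count of 1 did not stand out among them. These draws recombine only 3 within-group differences and varied widely, with 0 to 9014 genes at an unadjusted p under 0.05 in limma, against 719 observed. A count of lists also does not test oxidative phosphorylation itself.

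Replication-dependent histone genes were lower for 27 of 28 members (median -0.101, adjusted p = 0.055 in camera), with H2AC6 at -0.21 ± 0.10 (SE), and did not pass. They passed in the fit on the 4 arrays compared (adjusted p = 0.013), with trended and robust moderation (adjusted p = 0.041) and without DMSO replicate 1 (median -0.239, adjusted p = 6.23e-07), but their median was 0.010 without DMSO replicate 2. With an estimated correlation they did not (adjusted p = 0.883 with an estimated correlation), and the adjusted p ranged from 6.23e-07 to 0.883 over 20 alternatives.

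Further lists did not pass the test. Inflammatory adhesion molecules and chemokines were lower for 16 of 27 members (median -0.111, adjusted p = 0.099), with the chemokine gene CXCL1 at -0.41 ± 0.11 (SE) and the cytokine gene IL6 at -0.27 ± 0.10 (SE). Leukocyte markers were lower for 11 of 13 (median -0.077, adjusted p = 0.105), and smooth muscle and pericyte markers for 8 of 12 (median -0.083, adjusted p = 0.183). Leaving out combination replicate 2 brought the medians of the inflammatory list to -0.047 and of leukocyte markers to -0.013, and leaving out DMSO replicate 2 that of smooth muscle markers to -0.042. Targets of p53 were lower for 21 of 28 (median -0.077, adjusted p = 0.143) and pro-apoptotic genes for 16 of 23 (median -0.050, adjusted p = 0.143), with the death receptor gene FAS, a member of both, at -0.36 ± 0.13 (SE). Mitotic genes were lower for 27 of 47 (median -0.031, mean 0.006, adjusted p = 0.463), with CCNB2, a mitotic cyclin gene, at -0.46 ± 0.11 (SE), and their median turned to 0.001 when quantile normalized again. They passed without DMSO replicate 2 (median -0.092, adjusted p = 0.006), while the median was 0.016 without DMSO replicate 1. Over 20 alternatives the adjusted p of mitotic genes ranged from 0.006 to 0.932 (adjusted p = 0.932 with an estimated correlation). Adjusted over the list alone, TGFB2 at -0.44 ± 0.10 (SE) was called among YAP/TAZ targets (adjusted p = 0.030) and among TGF-beta and BMP targets (adjusted p = 0.041). The cation channel gene TRPC1 at 0.60 ± 0.13 (SE) was called among calcium handling genes (adjusted p = 0.038), and LYZ, the lysozyme gene, at -0.52 ± 0.11 (SE) among leukocyte markers (adjusted p = 0.018). Each had an adjusted p of 0.996 over all genes. The sign of the median and the direction of the test differed for 2 lists.

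Both comparisons used the same 2 DMSO arrays. Their log2 differences had a correlation of 0.512 over genes, which are not independent replicates, against a median of 0.499 in 100 simulations of unchanged groups with independent noise. The covariance was 0.00720 against a simulated 0.00755. With noise drawn from the within-group differences, the correlation had a median of 0.632 and ran from -0.944 to 0.993. The 2 comparisons shared 0 called genes. An unadjusted p under 0.05 in both was reached by 77 genes, of which 76 (98.7%) had the same direction, TXNIP and H2BC12 among them. In the simulated unchanged groups with independent noise, a median of 207 genes did so, 98.6% of them in the same direction, and with noise drawn from the within-group differences the median was 1 and the upper quantile 3110. The simulations were not matched to the 248 and 719 genes under 0.05 in the 2 comparisons, and the second kind ran from 0 to 3110. They therefore cannot decide whether the overlap exceeds what the shared DMSO arrays alone give. Part or all of it may come from the shared arrays. With telmisartan against DMSO replicate 1 and the combination against DMSO replicate 2, the correlation was -0.209, and the other way round it was 0.139. Noise drawn from the within-group differences gave correlations from -0.980 to 0.940 and from -0.964 to 0.968, too wide to decide. Each of these correlations rests on a single DMSO array per comparison.

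The third comparison asked what adding amlodipine changed in cells given telmisartan. PYROXD1, an oxidoreductase gene, differed by 0.83 ± 0.28 (SE, n = 2 per group), but by 0.40 without telmisartan replicate 2. The difference of PLA2G10, a secreted phospholipase gene, was -0.78 ± 0.11 (SE; 95% confidence interval -1.03 to -0.52). TAS2R46 differed by 0.70 ± 0.14 (SE), the zinc-finger gene ZNF721 by 0.69 ± 0.40 (SE), or 0.31 without combination replicate 2, and ADAM21, a membrane metalloprotease gene, by -0.68 ± 0.14 (SE). None passed the test. PLA2G10 and ADAM21 were dim, at 4.38 ± 0.13 and 4.83 ± 0.17 (SD, n = 2) with the combination.

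None of the fixed genes passed the test in this comparison. PPARG differed by -0.15 ± 0.14 (SE), CDKN1A by -0.13 ± 0.10 (SE), VCAM1 by -0.12 ± 0.14 (SE), NOS3 by -0.09 ± 0.10 (SE), KDR by 0.08 ± 0.11 (SE), MKI67 by 0.07 ± 0.21 (SE), CCNB1 by -0.04 ± 0.09 (SE) and MCM2 by 0.04 ± 0.11 (SE). AGTR1 differed by -0.02 ± 0.13 (SE), and median centring, which shifted all genes alike by 0.022, turned its sign. Leaving out 1 array turned the signs of MKI67 (-0.24 without telmisartan replicate 2), AGTR1 (0.17 without telmisartan replicate 2), PPARG, VCAM1 and MCM2, and moved NOS3, CCNB1, CDKN1A and KDR by more than 1.5 times. With limma, 0 of 18417 genes were called and the smallest adjusted p was 0.9998. An unadjusted p under 0.05 was reached by 522 genes (2.83%), below the share of 0.05 that uniform p-values would give. By more than 1.5-fold, 11 genes differed, and 27.2% of genes kept the order of all 4 arrays.

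None of the 43 lists was called between the combination and telmisartan by camera with the preset correlation (smallest adjusted p = 0.183), camera with an estimated correlation (0.965) or fry (0.712). Inflammatory adhesion molecules and chemokines were lower for 20 of 27 members (median -0.111, adjusted p = 0.20), with CXCL1 at -0.38 ± 0.11 (SE) and the innate immune receptor gene TLR2 at -0.26 ± 0.10 (SE). Beside it, leukocyte markers were lower for 12 of 13 (median -0.101, adjusted p = 0.183), and smooth muscle and pericyte markers for 9 of 12 (median -0.100, adjusted p = 0.608). Without combination replicate 2 these 3 medians were -0.029, -0.019 and -0.022. Targets of p53 were lower for 21 of 28 (median -0.079, adjusted p = 0.210), with TP53I3 at -0.30 ± 0.10 (SE) and DDB2, a DNA damage recognition gene, at -0.19 ± 0.10 (SE). The p53 list passed without telmisartan replicate 2 (median -0.086, adjusted p = 0.005), and its adjusted p ranged from 0.005 to 0.965 over 20 alternatives (adjusted p = 0.965 with an estimated correlation). Endothelial identity genes were lower for 18 of 25 (median -0.039, adjusted p = 0.733), with the transcription factor gene SOX7 at -0.28 ± 0.10 (SE), and with a median of -0.009 without telmisartan replicate 2. Calcium channel and calcium handling genes were lower for 15 of 26 (median -0.015, adjusted p = 0.733), and the same shift of all genes turned their median positive. The median log2 difference over all genes was itself -0.031 in this comparison. Endothelial identity genes lay close to that value and calcium handling genes above it, so neither list stood out as lower than the other genes. Of all genes that kept the order of the 4 arrays, 3662 were lower and 1353 higher. The sign of the median and the direction of the test differed for 13 lists.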

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

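The crossed pairing, the tests of every row of the table and the use of a different DMSO array for each comparison were chosen after seeing the data; the other alternatives were not. The count of called genes stayed at 0 under each of 20 alternatives in each comparison. Unadjusted p under 0.05 was reached by 68 to 847 genes for telmisartan against DMSO, 285 to 1893 for the combination against DMSO and 139 to 1569 for the combination against telmisartan. None of 759 values for 42 named gene results passed the threshold (smallest adjusted p = 0.142), and 735 kept their sign.

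The replicate numbers are not known to mark a shared donor, batch or day. With the replicate block, the count of calls was 0 in all 3 comparisons, with 174, 514 and 365 genes at an unadjusted p under 0.05, and 10 lists passed in place of 7. The block gave calls to PPAR targets and integrated stress response genes for telmisartan against DMSO (adjusted p = 0.049 for both, adjusted p = 0.97 with an estimated correlation) and to histone genes for the combination against DMSO (adjusted p = 0.029, adjusted p = 0.883 with an estimated correlation). Differences between replicates 1 and 2 correlated at 0.493 between DMSO and telmisartan, -0.409 between DMSO and the combination and -0.406 between telmisartan and the combination. With crossed pairing as a block, 0 genes and 9 lists were called.

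List calls moved more. Of 2553 alternative values of lists, 41 lost a call, 34 gained 1, and in 6 the direction of camera's test turned with a call in at least 1 of the settings. The test's direction need not be the sign of the median: under quantile normalization again, ribosomal protein genes lost their call while their median turned to 0.009. Leaving out single arrays, the median of mitotic genes ranged from -0.167 to 0.074 for telmisartan against DMSO and from -0.081 to 0.062 for the combination against telmisartan. In the same way, histone genes ranged from -0.196 to 0.085 and from -0.177 to 0.094 in the same comparisons. The medians in the fits whose test turned were 0.025 and 0.074 for mitotic genes and 0.054 and 0.085 for histone genes against DMSO, and -0.081 and 0.094 against telmisartan, the former from a median of -0.005 whose test pointed up. Fewer arrays entered these fits, and a lone array was assumed to vary like the other groups; the cause was not tested further. Each of the 7 list calls was lost under quantile normalization again and with an estimated correlation, and none of these lists passed in fry, which tests against no change. Under quantile normalization the medians against DMSO with telmisartan stayed at -0.039 for mitotic genes, -0.080 for heat shock proteins, -0.043 for histone genes and -0.041 for metallothioneins. These medians did not vanish, but camera compares a list with the other genes, whose median under this scaling was not set beside them. A loss of part of that difference is therefore not excluded. Oxidative phosphorylation had -0.022, and -0.044 with the combination. Signal over background was not used here; dropping the dimmer part of the genes left 0 called.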

Other observations

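Of the tests in this part, the draws of arrays without a treatment effect were set before their result was seen, and the tests of gene length, small RNA genes, H2BC12 by chance and the histone genes as a set were chosen after the result was seen. Genes named in the next paragraph were chosen after their values were seen.

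With the combination against DMSO, targets of liver X receptors, sensors of oxidised cholesterol, were higher for 9 of 11 members (median 0.108, adjusted p = 0.068 in camera, adjusted p = 0.876 with an estimated correlation). They passed under quantile normalization again (adjusted p = 0.041), with trended and robust moderation (adjusted p = 0.047) and without DMSO replicate 2 (adjusted p = 0.011), but not without combination replicate 1 (adjusted p = 0.233), where the median was -0.00007. Over 20 alternatives the median ranged from there to 0.154 and the adjusted p from 0.011 to 0.876. Among the members, the cholesterol exporter genes ABCG1 and ABCA1 differed by 0.34 ± 0.13 (SE) and 0.18 ± 0.09 (SE), and SREBF1, a regulator of lipid synthesis, by 0.28 ± 0.12 (SE). Genes of cholesterol synthesis and uptake were lower for 11 and higher for 8 of 19 members (median -0.015, adjusted p = 0.512), which shows no common direction. Among the lower ones were the sterol synthesis enzyme genes MSMO1 at -0.56 ± 0.13 (SE), CYP51A1 at -0.33 ± 0.10 (SE) and SQLE at -0.25 ± 0.09 (SE). Genes of the unfolded protein response were lower for 21 of 23 members against DMSO (median -0.083, adjusted p = 0.099, adjusted p = 0.876 with an estimated correlation). They passed with trended and robust moderation (adjusted p = 0.047) and without DMSO replicate 2 (adjusted p = 0.006), but under quantile normalization again the median was -0.038 (adjusted p = 0.558). Over 20 alternatives the median ranged from -0.133 to -0.036 and the adjusted p from 0.006 to 0.876.

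A first pattern is that 6 lists lay lower with telmisartan than with DMSO. A candidate explanation is noise shared by many genes between arrays. In 100 sets of arrays drawn from the within-group differences alone, 92 called at least 1 list and the median number was 2.5, but 0 of 100 reached 6 and the highest was 5. The bound set beforehand, fewer than 5 of 100 draws, was therefore met, which counts against shared noise of the kind drawn. That the bound was too weak to exclude shared noise was decided after this result was seen. The reason is that the draws recombine only 3 within-group differences. Camera with a correlation estimated from the same arrays called 0 lists (smallest adjusted p = 0.97). With 3 residual degrees of freedom it had little power, so that result is no evidence for shared noise. Shared noise and an effect of telmisartan therefore cannot be told apart here.

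A second pattern is the split of the arrays across the treatment groups. The correlation of the replicate difference with gene length followed it, at 0.307 in DMSO, 0.175 in telmisartan and -0.234 in the combination. The share of variance of the first component was still 0.444 after each array's trend over gene length was removed, which argues against gene length as its main source but not as a part of it. For 20 small nuclear RNA genes, replicate 1 minus replicate 2 had medians of -0.459 in DMSO, -0.112 in telmisartan and -0.346 in the combination. For 175 small nucleolar RNA genes the medians were -0.237, -0.026 and -0.116. These genes were thus lower in replicate 1 in all 3 groups and followed the split in 2 of 3, short of the 3 of 3 asked for. A count of 3 signs cannot decide whether a difference in small RNA yield had a part in the split. Differences in culture, donor or array handling stay open, since the labels used here give none, and no biological explanation was tested, although mitotic and histone genes followed the split.

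The last pattern is H2BC12, lower in both treated groups. Chance among the 18417 genes tested may account for it, since the smallest of as many independent p-values would be as small with a probability of 0.548. That probability uses the p-value of telmisartan against DMSO alone and assumes uniform p-values. Only 1.35% of genes had an unadjusted p under 0.05 in limma there, so it may be overstated. The other histone genes argue against histone transcripts varying together between arrays as the whole cause of the difference in H2BC12. The 28 listed had a median of -0.054 (quartiles -0.096 to -0.019) with telmisartan, against -0.90 for H2BC12. Both treated groups were compared with the same DMSO arrays, so they are not independent evidence of an effect, and a biological effect of telmisartan stays open.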
